A study of Corynebacterium glutamicum R with 4 samples.

How the data were processed

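Transcript levels of Corynebacterium glutamicum strain R were measured in the wild type and in a mutant lacking rsdA, both harvested in exponential growth from nutrient-rich A medium with glucose. Per the labels' protocols, total RNA was reverse transcribed and the cDNA carried the dye Cy3 through an indirect labelling system, so each array has 1 colour. The 4 arrays are 2 of the wild type and 2 of the mutant, and the labels number them by experiment. The series describes its 2 experiments as independent and says no more about separate cultures, so the p-values measure the spread between these samples, part of which may be technical.

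Per the file headers, the arrays were scanned on 1 channel and extracted with Agilent Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08; the submitters' processing notes name version 10.5.5.1. The deposited scanner files give a processed intensity for each spot, which per the file headers is background-subtracted within its array and not normalized between arrays, as well as median spot and background intensities and outlier, saturation and detection flags. The series' deposited value table holds log2 values. Against the scanner values of 36697 probes with a single spot, the difference between its mutant and wild-type columns equalled the scanner difference plus a constant per experiment, 0.0673 and 0.212 on the log2 scale, with a largest departure of 0.00189. Its columns are centred within each experiment and have medians of −0.0362 and 0.0362 in experiment 1 and −0.101 and 0.101 in experiment 2. The origin of the constants is not given in the sources used here.

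Each array carries 45220 spots, of which 43803 spots of 40204 probes are not controls. Probe names fall into a series of 3278 probes printed as 2 or 3 spots each, called multi-spot probes here, a forward series of 18462 and a reverse series of 18449 tiled probes with 1 spot each, and 15 probes with 10 spots each. The files do not pair these probe IDs with genes, and 0 of them occurred in the reference table of locus tags, which is for another strain. Each probe was therefore tested as a feature of its own in place of a gene. No probe is assigned to rsdA or sigD here, and the 19 gene lists fixed before the data were examined, with their camera and fry tests, were not run. The genome build behind the probes is not given in the sources used here.

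The processed intensity was taken to log2, spots flagged as outliers were left out, each array's 75th percentile over non-control spots was subtracted, and the spots of a probe were averaged. A probe entered the test if it was well above background on at least 2 of the 4 arrays, which kept 35391 probes: 3252 multi-spot, 16018 forward, 16106 reverse and the 15 others. Mutant and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are mutant minus wild type. A probe that was not well above background on either array of a group has a bound only: its fold is that of the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. The p-value printed beside such a bound comes from the signals as measured and does not test the bound. Such a bound belongs to this background treatment and scaling, and another treatment can give a smaller change. On simulated data with 200 changed probes among 35391, the fit of all probes recovered 7% of changes of 1 and 91% of changes of 2 on the log2 scale. It gave 12 false among 110 calls, a larger share than the threshold of 0.05. At that share of changed probes, single probes carry little power for 2-fold changes.

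After that result was seen, 3 further ways to read the arrays were added. The multi-spot probes were fitted and adjusted on their own (3252 tests; simulated recovery 98% and 100% for the same sizes). That simulation gave 19 false among 217 calls, also a larger share than the threshold of 0.05. Means of 5 consecutive tiled probes on 1 strand, with at least 3 kept, were fitted as 6787 windows (simulated recovery 94% and 100%, 9 false among 203 calls). Runs of at least 4 consecutive kept probes were counted in which each probe changed by at least 1 on the log2 scale, in the same direction, in both experiments, against 10000 shuffles of the probes' order within a strand. Tested on simulated data with independent probes, the run count found 10 of 10 planted runs at the median over 20 simulations. Without planted runs 0 of 20 simulations gave a p under 0.05. These held a median of 0 runs, so that outcome was all but fixed. The simulations leave out the correlation of neighbouring probes and do not test the shuffle under it. The reverse series was placed against the forward series from levels alone. Read backwards, its levels and those of the forward series correlated with Spearman's rho of −0.514 across 18458 probe pairs. This followed a search, for each 2000 forward probes, for the offset of up to 60 probes with the most negative rho. In the same order, without a search, rho was 0.0505. With the search, the most negative rho of each 2000 reached −0.135 in the same order, and lay between −0.302 and −0.559 backwards. The offset was set for each 2000 forward probes, since it drifts along the series. This gives an approximate place, whose error was not measured.

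The number of arrays limits the precision. Of the non-control spots, 91.6% and 83.0% were well above background on wild-type arrays 1 and 2, and 87.7% and 88.3% on mutant arrays 1 and 2, and 0 were saturated. The arrays of experiment 1 share a slide and a scan, as do those of experiment 2, so the slide is the same block as the experiment number. The experiment numbers were taken to pair the samples because the series describes 2 independent experiments and each lies on its own slide; the deviations of same-numbered samples from their group means correlated with 0.214 across all kept probes, which are not independent replicates.

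The rule for probes named in the text, fixed before the data were examined, took up to 12 risers and 12 fallers past the threshold with at least a 2-fold change, non-overlapping arrays and detection on both arrays of the brighter group, filled to 6 in each direction with the largest changes of the same sign in both experiments at an unadjusted p under 0.05. Because the IDs stand for no named gene, only the first 2 in each direction are printed. The same tests were repeated under settings fixed in advance: normexp background with quantile normalization, quantile normalization, median centring, a percentile over probes detected on all arrays, 2 other filters, a median over spots, an intensity trend with a robust prior, the experiment or slide as a block, each array left out, limma's treat against a 1.2-fold change, and the deposited value table. The files hold no mean spot signal, so normexp with an offset of 50 used the median spot intensity. Maps and runs were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.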

Results

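Gene expression of Corynebacterium glutamicum R, a soil bacterium with a mycolic acid cell envelope, was compared between the wild type and an rsdA deletion mutant in exponential growth. RsdA is the anti-sigma factor of SigD, an alternative sigma factor whose known targets include genes of mycolate synthesis. Each genotype was measured on 2 single-colour arrays, 1 from each of 2 independent experiments, and each experiment's pair of arrays shared a slide. The arrays tile both strands, with a further series of 3278 probes printed as several spots. The 75th percentile of the processed signal was 4627 and 5453 on wild-type arrays 1 and 2, and 3492 and 3702 on mutant arrays 1 and 2. Levels below are log2 signals relative to that percentile of their own array. Across 35391 kept probes Pearson's r was 0.988 between the wild-type arrays and 0.993 between the mutant arrays, and 0.988 and 0.978 between the genotypes on slides 1 and 2. Probes are not independent replicates. The files do not pair probe IDs with genes, so no probe is assigned to rsdA or sigD, and the label of the mutant is not checked here against the deleted gene.

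The question of the comparison is which transcripts differ when rsdA is absent. A single stretch of 5 consecutive forward-strand probes lost nearly all of its signal in the mutant. It is the longest forward run with a log2 loss of at least 4 in each experiment, a cutoff not fixed in advance. In the wild type the mean level of these probes was 3.27, and 3 of the 5 were not well above background on either mutant array. Probe CGRfwd04356 had a level of 3.61 ± 0.0301 in the wild type (SD, n = 2), was not well above background on either mutant array and was at least 3881-fold lower there (limma, adjusted p = 0.000414). Probe CGRfwd04359 had 3.20 ± 0.478 in the wild type (SD, n = 2), was likewise not well above background in the mutant and was at least 2923-fold lower (limma, adjusted p = 0.00784). The p-values are those of the signals as measured, undetected ones included, and not of the bounds. The bounds are those of the processing described above. With normexp and quantile normalization together the log2 changes of CGRfwd04356 and CGRfwd04359 were −9.76 and −9.29, smaller losses than the bounds. The fourth probe of the stretch kept a mean mutant level of −2.09 and changed by −5.43. The forward probe just before the stretch changed by −4.39 (−3.38 and −5.40 in the 2 experiments) and missed the cutoff in experiment 1 alone. The probe just after the stretch changed by 0.249.

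A multi-spot probe also fell, by at least 2495-fold with the same processing (limma, adjusted p = 0.00634). With normexp and quantile normalization together the log2 change of this probe was −9.10. Its spots had levels of 2.86 and 2.84 on wild-type array 1 and of 3.09 and 3.12 on wild-type array 2, and the probe was not well above background on either mutant array. The multi-spot probe numbered directly before it rose 2.08-fold in the mutant, by 1.06 ± 0.126 (SE) on the log2 scale (limma on the multi-spot probes alone, adjusted p = 0.0206), and the probe numbered directly after it changed by −0.851 ± 0.307 (SE) and did not pass (adjusted p = 0.122). On the reverse strand, 3 of the 5 probes placed opposite the lost stretch were at least 2-fold lower in both experiments. Among all kept reverse probes 2.28% were.

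**Figure D1:**
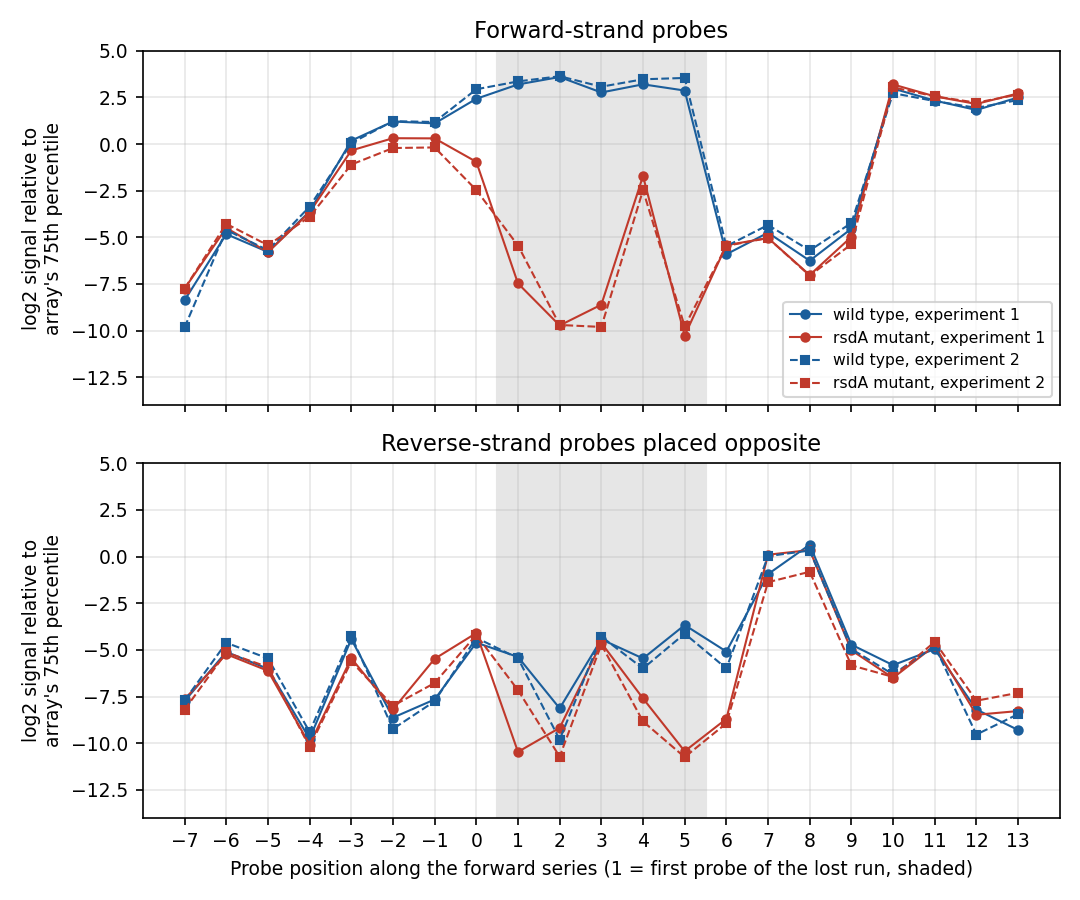
Log2 signal relative to each array's 75th percentile (vertical axes) for forward probes around the lost stretch (upper panel) and for the reverse probes placed opposite (lower panel), by probe position, with 1 line per array. The placement of the reverse probes is approximate, and its error was not measured. Within the shaded stretch of 5 positions the wild-type arrays average 3.27, while both mutant arrays fall far below them, least at position 4; the mutant points at positions 2, 3 and 5 are not well above background and have no exact level.

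Over all 35391 probes, 5 passed the threshold and all 5 were lower in the mutant. They were 3 forward probes of the lost stretch, the lost multi-spot probe and 1 of the reverse probes opposite. That reverse probe was at least 21.3-fold lower (limma, adjusted p = 0.0287), but its log2 change was −2.41 with normexp and quantile normalization together. No probe was higher past the threshold (0 by limma), although 8934 probes (25.2%) had an unadjusted p under 0.05 and 268 probes shared an adjusted p of 0.0569. At an adjusted p under 0.1, 1103 probes were higher and 1779 lower. Under the naming rule the first 2 upward, which did not pass, were CGRfwd06787, with a log2 change of 2.97 ± 0.279 (SE) although it was well above background on only 1 of the 2 wild-type arrays, and CGRfwd11919, which was not well above background in the wild type and was at least 4.36-fold higher (limma, adjusted p = 0.0569 for both). With normexp and quantile normalization together their log2 changes were 1.24 and 0.837, while with quantile normalization alone that of CGRfwd06787 was 3.07. The counts depended on the processing: 203 were higher and 144 lower with median centring, 2 and 7 with quantile normalization, 0 and 6 with the percentile over probes detected on all arrays, 356 and 282 with normexp and quantile normalization together, and 1332 and 1357 with the deposited value table and the experiment as a block. With the experiment as a block in the scanner values 4 probes passed, and the third forward probe of the stretch had an adjusted p of 0.0785. The count was 724 without wild-type array 1, 0 without mutant array 1, 5 without wild-type array 2 and 0 without mutant array 2, each time with 1 array standing for its genotype.

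Fitted and adjusted on their own, 288 of the 3252 multi-spot probes passed the threshold. Of these, 167 rose and 121 fell in the mutant, and 48 of the risers and 47 of the fallers changed at least 2-fold. This fit was chosen after the all-probe result was seen. In the all-probe fit 1 of the same 3252 probes passed, at the same log2 changes. There 779 of them had an unadjusted p under 0.05 (limma), against 1135 in their own fit. The larger count thus comes from the variance estimate and the adjustment, not from larger changes. The risers had a median log2 change of 0.830, and the fallers other than the lost probe one of −0.924. Direction went with level: 31.7% of the risers and 9.09% of the fallers lay above the array's 75th percentile (Fisher's exact test, p = 3.1e-06). That test takes probes as independent. Among all tested multi-spot probes 41.9% lay above it. Over all kept probes the brightest were also higher in the mutant than the rest, by 0.276 on the log2 scale. How far the direction of these calls follows level rather than genotype was not tested. The largest riser was 5.40-fold higher, with 2.55 on slide 1 and 2.31 on slide 2 (mean 2.43 ± 0.124, SE; adjusted p = 0.00633). The next was 4.34-fold higher, at 2.12 ± 0.124 (SE; adjusted p = 0.00863). Among the fallers, a probe with a wild-type level of 1.38 ± 0.0716 (SD, n = 2) was 4.64-fold lower in the mutant, at −2.21 ± 0.187 (SE; adjusted p = 0.00958). Across all tested multi-spot probes the folds of the 2 experiments correlated with r = 0.788. Within single slides, 49 multi-spot probes were at least 2-fold higher and 39 lower on slide 1, and 79 higher and 138 lower on slide 2, without a test.

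Multi-spot probes that changed lay beside each other in the numbering. Of the 288, 74 pairs of direct neighbours changed in the same direction, against 12.9 on average and at most 28 in 10000 shuffles (permutation p = 0.0001, the smallest they can give), and 10 pairs changed in opposite directions, against 12.3 on average. The shuffles treat probes as independent, whereas the levels of neighbouring multi-spot probes correlated with r = 0.401. The balance of risers and fallers depended on the scaling and on single arrays. By scaling, the percentile over probes detected on all arrays gave 138 higher and 144 lower, median centring 468 and 173, and the deposited value table with the experiment as a block 602 and 229. Median centring moved the median of all probes upward by 0.126 and the value table by 0.139. The number of multi-spot probes past the threshold was 33 without wild-type array 1, 524 without mutant array 1, 2 without wild-type array 2 and 13 without mutant array 2, and without mutant array 1 the balance turned, with 182 higher and 342 lower.

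**Figure D2:**
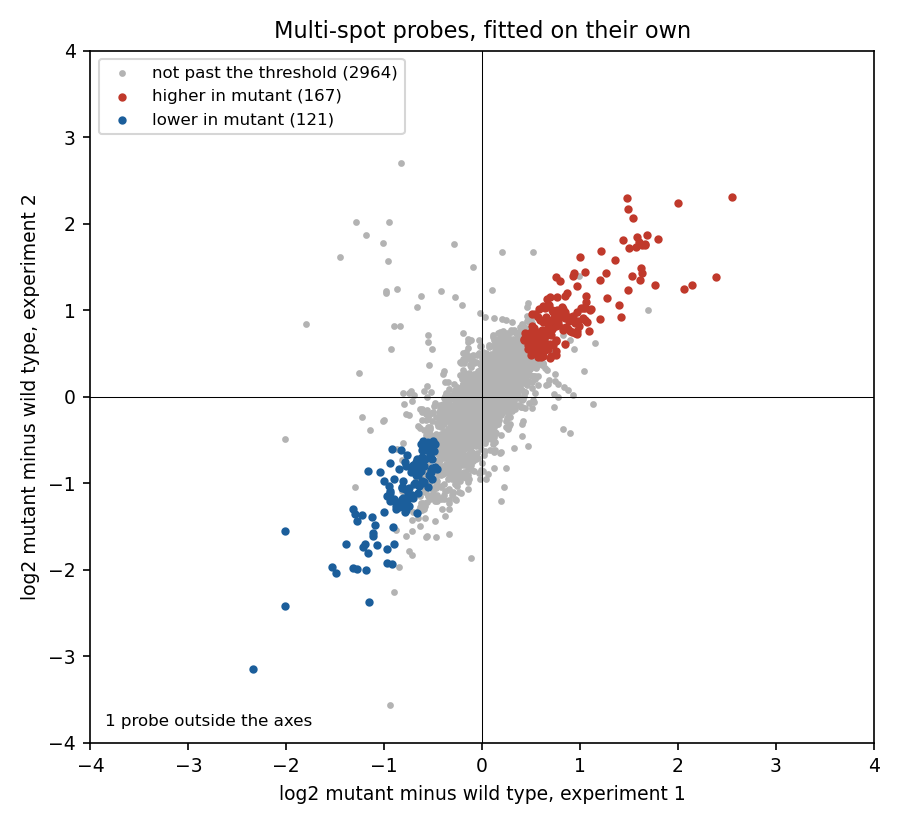
Log2 change, mutant minus wild type, of each multi-spot probe in experiment 1 (horizontal axis) and in experiment 2 (vertical axis), coloured by the limma result for both experiments together. The 167 risers and 121 fallers, 1 of which lies outside the axes, are drawn in colour over the probes that did not pass.

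Along the tiled strands part of the changes came in blocks. In 23 runs of at least 4 neighbouring probes every probe was at least 2-fold higher in the mutant in both experiments, and in 11 runs every probe was at least 2-fold lower. The risen runs held 172 of the 348 tiled probes that were at least 2-fold higher in both experiments. Of these runs, 11 lay on the forward strand and 12 on the reverse strand. The fallen runs held 62 of the 754 tiled probes that were at least 2-fold lower, so most lower probes lay outside runs. Of the fallen runs, 7 lay on the forward and 4 on the reverse strand. The longest risen runs spanned 18 and 15 forward probes, with mean log2 changes of 1.66 and 1.71, then 14 reverse probes with 1.72 and 12 forward probes with 1.84. In the run of 18 the mean was 1.57 in experiment 1 and 1.75 in experiment 2, and the SD over its probes was 0.181. A run of 11 reverse probes rose by 1.39 from a wild-type level of 1.96. The longest fallen run spanned 9 reverse probes, with a wild-type level of 3.45 and a mean change of −1.56 (−1.38 and −1.73 in the 2 experiments). A run of 7 reverse probes fell by 2.44 on the log2 scale. The lost stretch, with the probe before it, forms a fallen run of 6.

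Shuffling the probes gave at most 2 such runs per strand and direction in 10000 shuffles, with a permutation p of 0.0001 for each of the 4, the smallest they can give. Neighbouring tiled probes can report the same transcript, so a run is not a count of genes. A run ended at any probe that missed the cutoff or was not kept, so separate runs can be parts of the same block. The risen forward runs of 18 probes from number 3937 and of 4 probes from number 3956 lie this close. The shuffles treat probes as independent, whereas the levels of neighbours correlated with r = 0.789 on the forward and 0.798 on the reverse strand. The p-values therefore show that changed probes adjoin more than independent probes would, and not that genotype is the cause. The definition of a run was set after the folds were seen. A required change of 1.2 gave 13 risen and 7 fallen runs, a change of 0.8 gave 39 and 33, and normexp with quantile normalization gave 14 and 4.

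**Figure D3:**
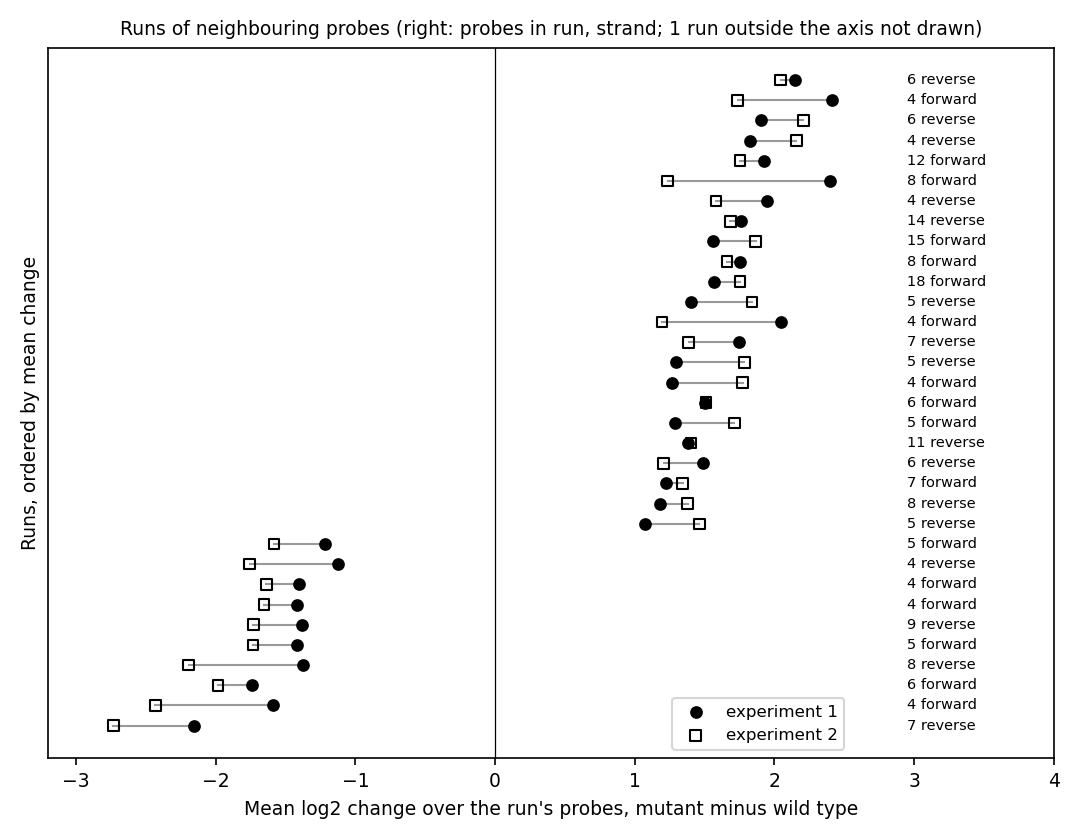
Mean log2 change over the probes of each run, mutant minus wild type, in experiment 1 (filled circles) and experiment 2 (open squares), with the number of probes and the strand at the right. The plot holds 23 risen and 10 fallen runs, which share their direction between experiments by definition; the run that holds the lost stretch lies outside the axis.

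Fixed windows of 5 tiled probes gave 514 changed windows of 6787, of which 197 were higher and 317 lower in the mutant, and 65 and 109 of these changed at least 2-fold. With the experiment as a block 1143 windows passed, 449 higher and 694 lower. The balance depended on the processing: 172 windows were higher and 391 lower with the percentile over probes detected on all arrays, 526 and 361 with median centring, 419 and 361 with quantile normalization, and 437 and 436 with normexp and quantile normalization together. The count was 471 without wild-type array 1, 1 without mutant array 1, 165 without wild-type array 2 and 1 without mutant array 2.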

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

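The fits of multi-spot probes and windows, the runs, the looser threshold, the value table with a block and the fit with outlier spots kept were chosen after seeing the data; the other settings were fixed before the data were examined. The 12 probes of the naming rule kept their direction in all 181 comparisons with another setting (replicate and identical slide block counted once). The rule took large changes of the same sign in both experiments, so the kept direction was largely set by that choice. In these comparisons 136 stayed on their side of the threshold, 13 no longer passed and 32 newly passed. All 5 probes lower past the threshold were among the calls under normexp with quantile normalization (638 probes past the threshold, 385 at least 2-fold), quantile normalization (9 and 9), median centring (347 and 347), an intensity trend with a robust prior (2150 and 1198), the value table alone (14620 and 1727) and the value table with the replicate block (2689 and 1722). Without a filter on dim probes 3 passed, 3 of them at least 2-fold, and with detection on all 4 arrays 1358 and 1000, which shared 0 with the 5 because that filter removes them. At an adjusted p under 0.1, 2882 probes passed. With outlier spots kept, a fit that was seen first, 7 passed, all lower. Multi-spot probes past the threshold numbered 641 with median centring, 515 with the trend, 1643 with the value table and 831 with its block, and those at least 2-fold 58 with normexp. Of the 288 multi-spot probes, 279 also passed with median centring, 254 with quantile normalization, 223 with normexp and 275 with the replicate block, which passed 350. Windows past the threshold numbered 873 with normexp, 780 with quantile normalization, 887 with median centring, 183 without a filter, 1052 with detection on all 4 arrays, 1354 with the trend, 1143 with the replicate block or the slide as a block, 3230 with the value table and 2179 with its block. The unblocked value table counts are too high by construction, since its columns mirror each other within an experiment. The replicate block ended 1 of the 5 calls over all probes, leaving 4. Runs numbered 39 risen and 33 fallen at a change of 0.8, 13 and 7 at 1.2, and 14 and 4 with normexp; with values raised to each array's lowest detected signal, a setting also chosen after seeing the data, they numbered 23 and 10. Leaving out 1 array gave from 0 to 724 probes past the threshold, with the same range for those at least 2-fold, from 2 to 524 multi-spot probes, from 2 to 193 of these at least 2-fold, and from 1 to 471 windows; the lone array of a genotype is then assumed to vary like the others. For the other counts that moved the cause was not tested. No probe was saturated, and each probe was tested as a feature of its own, so the saturation setting and the filter within gene means changed nothing and were not run; the gene lists with camera and fry, rsdA and sigD were not run because the files do not pair probes with genes. Signal over background limits the dim probes: the negative controls had a median processed signal of 6.67 on wild-type array 2, against 2.37 to 2.71 on the other arrays.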

Other observations

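The tests of missing DNA and of the lost multi-spot probe were chosen after their values were seen; those of nearby spots, of the brightest probes and of opposite strands were written down before their results. In both experiments 754 tiled probes were at least 2-fold lower and 62 of these lay in runs, while 348 were at least 2-fold higher and 172 of these lay in runs. The lost stretch included, some probes were detected in 1 genotype alone: 61 forward, 70 reverse and 3 multi-spot probes were well above background on both wild-type arrays and on neither mutant array, and 40, 51 and 0 the other way round. Those detected in the wild type alone were mostly dim there, with median levels of −6.87, −6.95 and −6.45. The lowest detected signals on the wild-type arrays were −8.62 and −7.72. Only 7, 7 and 1 of them were at least 8-fold lower, and 0 in each series were at least 8-fold higher the other way round. Across the 21 risen runs with at least 3 kept probes opposite, the opposite probes had a median change of the same sign in 11. Across the 11 fallen runs it was 10.

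Damage to the areas of the mutant arrays that hold the 5 spots of the lost stretch would lower the spots around them, but of the 30 nearest detected spots a share of 0 was at least 2-fold lower in both experiments, and at least 2263 other spots lay closer to each of the 5 than any other of the 5 did, which argues against it. For the lost multi-spot probe, damage to single spots is argued against by a loss at every spot in each experiment. With the processing described above the loss was at least 10.996 on the log2 scale, a bound against the lowest detected signal. The place of this probe relative to the stretch is not given in the sources used here. If the DNA under the stretch is missing from the mutant, the reverse strand should lose its signal too, and 3 of the 5 opposite probes were at least 2-fold lower in both experiments, also with values raised to each array's lowest detected signal; this count stayed at 3 with the placement moved by 1 to 3 probes in one direction, and was 2, 1 and 1 in the other. Against a complete loss, 1 opposite probe changed by only −0.312 and the fourth forward probe kept a level of −2.09. Just past the stretch, the reverse probe placed there changed by −3.27 while the forward probe changed by 0.249. A candidate explanation is that the stretch lies in the deleted DNA, since the design names a deletion, but the files do not place rsdA, and copies of the strand opposite to an abundant transcript may give the same loss.

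The brightest 10% of probes were higher in the mutant than the rest, by 0.276 on the log2 scale (0.243 in experiment 1 and 0.313 in experiment 2). An intensity bias between arrays that is unrelated to genotype should give such a shift between the arrays of 1 genotype as well. The same-genotype shifts were 0.0527 in the wild type and 0.117 in the mutant, and the larger was 0.424 of the shift between genotypes (0.482 against experiment 1 alone), under the bound of 0.5 set beforehand. This argues against such a bias as the whole cause, with 1 difference per genotype to judge by. A bias that goes with genotype, such as RNA yield or labelling, and a change of abundant transcripts both stay open and were not tested.

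The folds of dim reverse probes followed those of the bright forward probes opposite. Across 2705 such pairs they correlated with Spearman's rho of 0.287, against 0.0231 at a place 50 probes away, and with 0.287 when the lost stretch was left out. Labelled copies of the strand opposite to an abundant transcript may give this, and would also make the dim probe brighter where the bright one is. The levels' rho was 0.0859, below the 0.1 this needed and above the 0 that would exclude it, and it was 0.122 at the distant place, so the levels do not decide. Antisense transcripts stay open as well and were not tested, and of 21 bright probes that changed at least 2-fold in both experiments 11 had an opposite probe of the same sign.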
